A study of Homo sapiens with 3 samples.

How the data were processed

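The samples were 3 replicates of an easyCLIP experiment, a form of UV crosslinking and immunoprecipitation in which RNA bonded to a protein by UV light is recovered with the protein, cut short and sequenced. HEK293T cells, a line derived from human embryonic kidney that carries the SV40 large T antigen, were transfected with 750 ng of a vector for HA-tagged HNRNPA0 on a 15 cm plate, per the labels' protocols. Cells were irradiated at 254 nm with 0.3 J/cm2, and about 2 mg of lysate per replicate was bound to 22 uL of anti-HA beads and treated with RNase I at 0.02 U/uL for about 3 min. The 3' adapters carried a barcode that told the replicates apart and random bases usable as molecular identifiers, and the replicates were pooled after that ligation. Sequencing was paired-end at 150 bp with a target of about 30 M reads per sample, per the labels.

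The authors deposited 1 peak list per replicate in BED layout without a header, so peaks were called per sample and not on pooled samples. Coordinates were on hg38, and bedtools and deepTools were named without versions, per the submitters' processing notes. The aligner, the peak caller, its settings and the use of the molecular identifiers were not given in the sources used here. Each deposited line held a position, a strand, a p-value per peak from the authors' peak caller, a short stretch of nucleotides inside the peak, and a name made of an Ensembl gene ID, an index and a whole number. The deposited p-values were all under the threshold of 0.05, with no adjustment stated, and some were exactly 0. The whole number at the end of the name was read as the reads in the peak, and is called the read number here. The deposited lines do not name it. The reading rests on the layout and on its fall as the p-value rises among the peaks of a gene ID. Both values were ranked within each gene ID that had a set minimum of lines, and the ranks were pooled over each list. The Spearman correlation of these ranks across peaks was -0.53, -0.54 and -0.38 in the lists of replicates 1, 2 and 3. Peaks are not independent replicates, so no test was attached to that correlation. Neighbouring peaks can touch and may hold the same reads, so a sum of read numbers is a description and not a count of molecules, and no counting interval is given for shares of it. Reads per library outside peaks were not analysed here, so depth is known only as the read numbers in peaks.

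Lines with the same interval and strand under more than 1 gene ID were counted once, which removed 621 ± 78.2 lines per replicate (SD, n = 3). Genes were named by position from a RefSeq gene table of the matching human assembly, which gave symbols and intervals for 59716 genes and no strand. A gene ID was tied to a RefSeq gene that contained at least 90% of the centres of its peaks. Of 6583 gene IDs, 5737 were tied to 1 RefSeq gene, 640 to several and 206 to none. Where several genes covered a position, the gene ID and then the strand of peaks seen in unambiguous genes decided, readthrough genes and loci without a given symbol were set aside, and genes still tied were named jointly. A joint region counted for a gene only if that gene was the single protein-coding one, or the single one that was not an antisense RNA.

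Peaks of the 3 lists that overlapped by 1 bp or more on the same strand were merged into regions, and regions with a peak from all 3 replicates formed the main set. Peaks that only touched were not merged, so the number of regions of a gene can count 1 unbroken stretch more than once. Overlap between replicates was the share of the peaks of one list overlapped by another, as the mean of the 6 ordered pairs. It was compared with 100 random placements of the second list within the same genes by a one-sided permutation test whose smallest possible p is 0.0099. The planned placement with exons and introns apart needed an exon annotation, so placement anywhere in the same gene was used. Position along the gene was added after the files were seen. It used centres of regions in protein-coding genes of 5000 bp or more, against 100 random placements in the same genes, with two-sided permutation p-values and Benjamini-Hochberg adjustment over 4 classes. The distance that counted as near a gene end was 1000 bp.

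The 16 gene lists were fixed before the data were examined. For 14 of them, the number of members with a region in all 3 replicates was compared with 10000 random lists drawn from 20037 protein-coding genes and matched on gene length in 10 bins. The two-sided permutation p-values were adjusted by the Benjamini-Hochberg method over the 14 lists, and the smallest possible raw p is 0.0002. The mitochondrial and long noncoding RNA lists were counted without a test. RNA levels were not used here, and so no list was matched on expression.

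The genes named in the text followed a rule set before the data were examined. It took HNRNPA0, the 10 nuclear-encoded genes whose best peak ranked highest by p-value over the replicates, the 10 nuclear-encoded genes with most regions, and of each list up to 4 members with most regions and up to 2 without a region. Some genes that the rule took are not reported here. Genes outside the rule are said to be chosen after their values were seen. The planned searches for G-quadruplex motifs and short motifs, the parts of the naming rule that rested on them, the split into exons, introns and untranslated regions, and matching on exonic length needed a genome sequence or exon annotation and were not run.

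All 3 samples formed 1 group, no control library was used here, and no comparison between groups was made. Nothing in the labels says that the replicates came from separate cultures, so every SD measures only the spread between these samples, which may be technical. The p-values come from random placements, random gene lists or counts of genes, and measure no spread between replicates. The overlap, merging and list steps were tested on simulated data with 15000 peaks per list. With 2000 shared sites, 2002 regions were found in all 3 lists, and in a separate simulation without shared sites 1 region was. The simulated unshared peaks lay at random over protein-coding genes, and were less crowded than the real peaks. Random placement there gave an overlap of 0.402%, against 2.61% in the data. The simulation therefore does not tell how many regions of the data would arise without shared sites. In the list test over 20037 genes, 0.5% of 200 unchanged simulated lists were called. Lists of 25 genes were called in 23%, 75% and 100% of cases at 2, 4 and 8 times the background rate. These calls used an unadjusted permutation p under 0.05 and fewer random lists than the 10000 used for the data. The rates are therefore not those of the adjusted calls in the results. Alternatives were the stricter 50% of each list by p-value, an overlap of 50% of both peaks, strand ignored, chromosomes 1 to 22 and X without the HNRNPA0 gene, regions in 2 or more replicates, lists not matched on length, and each replicate left out. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.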

Results

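RNA crosslinked to HA-tagged HNRNPA0, an RNA-binding protein of the hnRNP A/B family, was mapped by easyCLIP in 3 replicates of transfected HEK293T cells, in a study of RNA G-quadruplexes and their protein partners. G-quadruplexes are four-stranded structures formed by guanine-rich nucleic acid. The 3 replicates formed 1 group, and the question the lists can answer is which RNAs, and which parts of them, held peaks in every replicate. The lists held 15661, 15486 and 17791 distinct peaks in replicates 1, 2 and 3, with a median width of 63 ± 1 nt and a median read number of 4 (n = 3). Peaks lay on the plus strand in 50.6% ± 0.236 of cases (SD, n = 3). Summed widths came to 996812, 986344 and 1164544 nt, and summed read numbers to 268608, 268445 and 221013.

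Mitochondrial ribosomal RNA held the highest peaks of all 3 lists. RNR1, the small-subunit ribosomal RNA of mitochondria, took 39.4% ± 8.34 of the summed read numbers, and RNR2, the large-subunit RNA, took 15.5% ± 2.37 (SD, n = 3). The highest peak lay in RNR1 at positions 1351 to 1504 of the mitochondrial genome, with read numbers of 25800, 27552 and 14976. RNR2 held 6 regions found in all 3 replicates, of which those at 2093 to 2103, 2104 to 2108 and 2109 to 2177 touch end to end. Among mitochondrial messenger RNAs, COX1, a subunit of cytochrome c oxidase, held 0.749% ± 0.125, ND6, a subunit of complex I, 0.643% ± 0.0822, ND4, another, 0.436% ± 0.122, and CYTB, a subunit of complex III, 0.241% ± 0.037 (SD, n = 3). Of 37 mitochondrially encoded genes, 16 held a region in all 3 replicates, and the transfer RNAs TRNA and TRNC were among the 21 that did not. All mitochondrial peaks together took 62.8%, 63.1% and 48.3% of the summed read numbers in replicates 1, 2 and 3. With each run of touching peaks counted once at its highest peak, the mitochondrial share was 35.8% ± 6.02 (SD, n = 3). The highest peak of ND6 had read numbers of 1072, 883 and 855. RNR1 and ND6 were chosen after their values were seen. No control library was used here, so these shares do not separate RNA crosslinked to HNRNPA0 from RNA recovered without it.

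The strongest peaks recurred in all replicates and the weakest seldom did. Of peaks with a read number of 50 or more, 92.0% ± 2.22 lay in a region found in all 3 replicates, against 3.52% ± 0.398 of peaks with a read number of 3, the lowest in the lists (SD, n = 3). Peaks with a read number of 3 made up 43.5% ± 1.75 of each list, and those with 20 or more made up 3.53% ± 0.359. Merging gave 38104 regions, of which 30913 held a peak of 1 replicate, 4819 of 2 and 2372 of all 3. On average 26.0% of the peaks of one replicate were overlapped by a peak of another, with a range of 23.7% to 27.3% over the 6 ordered pairs. Random placement within the same genes gave 2.61%, and the observed overlap was 9.97 times as high, with a one-sided permutation p of 0.0099, the smallest that 100 placements can give. Shifting each peak by 200 to 1000 nt, a setting chosen after the data were seen, gave 4.61% and a ratio of 5.63, so the size of the excess depends on how closely the random peaks follow the real ones. Across the 2372 regions in all 3 replicates, the highest read numbers had Spearman correlations of 0.79, 0.75 and 0.75 between replicates 1 and 2, 1 and 3, and 2 and 3. These correlations run across regions, which are not independent replicates.

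**Figure D1:**
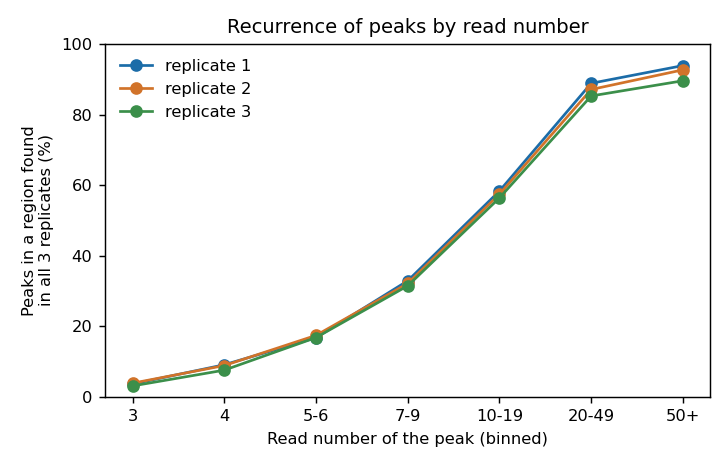
Share of peaks that lie in a region found in all 3 replicates (y axis, percent) by the read number of the peak (x axis, binned), with 1 line per replicate. The mean share was 3.52% at a read number of 3, 57.4% at 10 to 19 and 92.0% at 50 or more.

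The HNRNPA0 gene itself held strong peaks, and nearly all of them lay in one short stretch near its 5' end. The gene lies on chromosome 5 from 137745651 to 137754363 (hg38) and spans 8713 bp, with its peaks on the minus strand. Replicates 1, 2 and 3 had 5, 8 and 6 peaks there, with summed read numbers of 308, 358 and 340. A stretch of 899 nt from 137753155 to 137754053, which is 10.3% of the gene, held 98.5% ± 1.34 of the summed read number (SD, n = 3). The stretch ends 310 nt from the 5' end of the gene. The remaining 7814 nt of the gene held no peak in replicate 1 and 1 peak each in replicates 2 and 3, with read numbers of 9 and 7. Of the merged regions in the gene, 3 were found in all 3 replicates. The vector also carries HNRNPA0 sequence, and the lists do not tell RNA of the vector from RNA of the chromosomal gene.

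**Figure D2:**
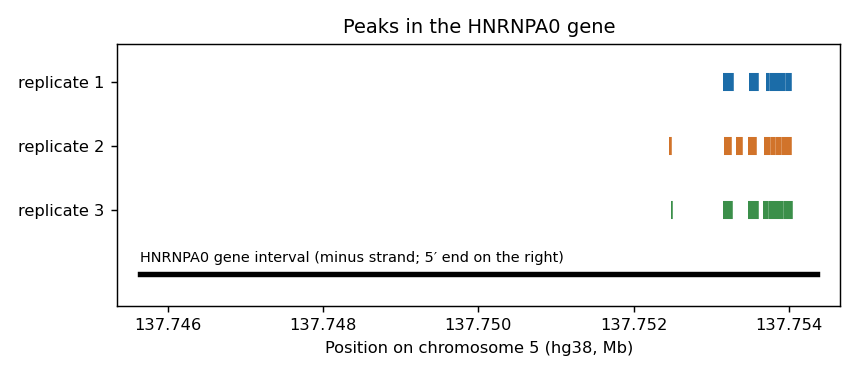
Peaks in the HNRNPA0 gene in each replicate (coloured blocks, 1 row per replicate) along chromosome 5 in Mb (x axis, hg38), with the gene interval as a black bar. The peaks of all 3 replicates crowd into a stretch of 899 nt near the 5' end, and single peaks of replicates 2 and 3 lie outside it.

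Regions found in all 3 replicates lay in 1295 genes, of which 1242 were protein-coding and 21 were long noncoding RNAs. XIST, the long noncoding RNA that silences an X chromosome, held 30 regions, more than any other gene, with 59.3 ± 5.13 peaks per replicate (SD, n = 3). XIST took 7.66%, 7.40% and 12.2% of the nuclear-encoded summed read numbers in replicates 1, 2 and 3. With each run of touching peaks counted once at its highest peak, these shares were 6.27%, 6.20% and 8.77%. Its highest region, at X from 73849795 to 73849977, had read numbers of 393, 405 and 770. Next by number of regions came EIF4G2, a translation initiation factor homologue, and SLIT2, an axon guidance ligand, with 13 regions each. NUCKS1, a chromatin-associated protein, and NAP1L1, a histone chaperone, held 12 each. Some regions of NUCKS1 touch end to end, such as 205715482 to 205715555 and 205715556 to 205715705, and its rank counts them separately. HNRNPA1, HNRNPA2B1 and the ribosomal protein gene RPL4 held 10 each, and the chromatin remodeller gene HELLS and HNRNPH1 held 9 each. In all, 476 genes held 2 or more regions, 65 held 5 or more and 8 held 10 or more.

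The regions of XIST fell into groups, with 20 of the 30 between 73842762 and 73849977, nearer its 5' end, 9 between 73822490 and 73825154, and 1 between these groups. SLIT2 spans 368657 bp and had 91.3 ± 11.9 peaks per replicate with a highest read number of 24.3 ± 6.35 (SD, n = 3). Of its 13 regions, 3 were left in the stricter 50% of each list by p-value, and 22 to 25 were counted with 1 replicate left out, against 14 to 20 for EIF4G2. NAP1L1 and HELLS had highest read numbers close to that of SLIT2, at 26.3 ± 6.66 and 28.3 ± 4.62, with 21.0 ± 2.00 and 28.7 ± 6.81 peaks (SD, n = 3). EIF4G2 had 24.0 ± 4.58 peaks with a highest read number of 67.3 ± 10.2, and NUCKS1 had 20.7 ± 2.52 peaks with a highest read number of 168 ± 4.51 (SD, n = 3).

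**Figure D3:**
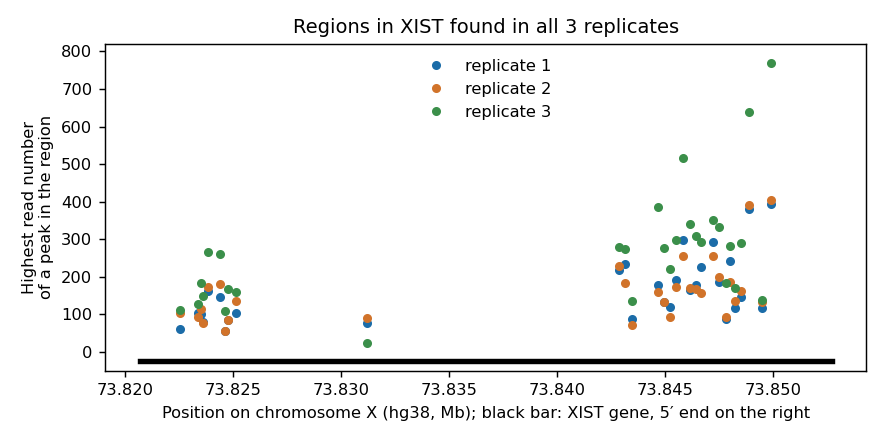
Highest read number (y axis) of the 30 regions in XIST found in all 3 replicates, by position on chromosome X in Mb (x axis, hg38), with 1 colour per replicate and the gene as a black bar. The highest region had read numbers of 393, 405 and 770 in replicates 1, 2 and 3.

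Ranked by their best peak, the leading nuclear-encoded genes were HSP90AA1, TRU-TCA1-1, KIF5C, XIST, AMOT, NUCKS1, TMEM107, WDR74, AGBL5 and ORC6. The peak of HSP90AA1, an inducible cytosolic chaperone, lay on chromosome 14 from 102084782 to 102084998 with a highest read number of 215 ± 7.57 (SD, n = 3). That of AMOT, the gene of the scaffold protein angiomotin, lay on X from 112776986 to 112777207 with 180.0 ± 11.5. TRU-TCA1-1, a selenocysteine transfer RNA gene on chromosome 19 from 45478601 to 45478687, had 242 ± 101. Several of the others were regions shared with a second gene. The region counted for TMEM107, on chromosome 17 from 8173454 to 8173584, with 107 ± 4.51, also lies in the interval of SNORD118, the U8 small nucleolar RNA. The region counted for WDR74, on chromosome 11 from 62841643 to 62841788, with 78.0 ± 6.08, also lies in that of RNU2-2, a U2 small nuclear RNA gene. The region counted for KIF5C, a kinesin gene transcribed from the plus strand, lay on the minus strand of chromosome 2 from 148881726 to 148881820, the strand of its antisense transcript KIF5C-AS1, with which it was named jointly. Its read numbers were 350, 265 and 128, and the count for KIF5C follows only from the rule for joint regions. AGBL5 and ORC6 held 1 region each, with highest read numbers of 72.3 ± 17.5 and 76.7 ± 22.5 (SD, n = 3).

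Of 18 long noncoding and other noncoding RNAs listed beforehand, 13 held a region in all 3 replicates. MALAT1, an abundant RNA of nuclear speckles, held 7 regions and 0.628% ± 0.124 of the nuclear-encoded read numbers, and its regions were named jointly with the antisense transcript TALAM1. NEAT1, the scaffold of paraspeckles, also held 7 regions, with 0.168% ± 0.065, and its highest region had read numbers of 16, 15 and 32. GAS5, a host gene of small nucleolar RNAs, and JPX, a noncoding gene near XIST, held 4 each. CYTOR and KCNQ1OT1 held no peak in any replicate.

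Regions found in all 3 replicates were concentrated near the 3' ends of protein-coding genes. Of 2072 regions in 1170 protein-coding genes of 5000 bp or more, 41.0% had their centre in the final 10% of the gene, against 10.0% under random placement in the same genes. The first 10% of the gene held 4.20% of regions against 10.0% placed. The last 1000 bp held 16.0% against 4.02%, and the first 1000 bp held 2.27% against 4.01%. Each of the 4 differences had an adjusted two-sided permutation p of 0.0198, the smallest that 100 placements can give. With all peaks of each list, the final 10% held 32.4% ± 0.777 and the first 10% held 7.23% ± 0.772 (SD, n = 3). Gene intervals include introns, and exons, introns and untranslated regions were not told apart here. Random placement over whole gene intervals therefore cannot separate a preference of binding for 3' ends from the layout of exons in spliced RNA.

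**Figure D4:**
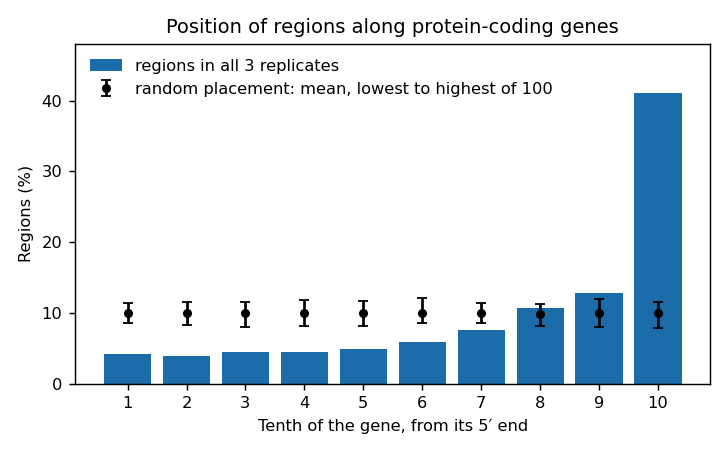
Share of the 2072 regions found in all 3 replicates (bars, y axis in percent) by position along protein-coding genes from the 5' end (x axis, 10 equal parts). Black points are the mean of 100 random placements in the same genes with their lowest and highest value; the last part holds 41.0% of regions against 10.0% placed.

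Genes for hnRNP proteins and SR splicing factors held regions more often than random genes of the same length. Of 24 hnRNP genes, 18 held a region in all 3 replicates, against 1.41 in random lists (adjusted permutation p = 0.0004). The 18 include HNRNPA0 itself, and on chromosomes 1 to 22 and X without that gene 17 did (adjusted permutation p = 0.0004). Of 16 genes for SR and SR-like splicing factors 12 did, against 0.87 (adjusted permutation p = 0.0004). HNRNPA1 and HNRNPA2B1 led with 10 regions each, followed by HNRNPH1 with 9 and HNRNPC, which binds uridine-rich nuclear RNA, with 8. HNRNPAB and HNRNPF held no such region. Among the SR genes SRSF3 led with 8 regions and a highest read number of 47.7 ± 0.577 (SD, n = 3), and SRSF1, SRSF10 and SRRM2 held 3 each, while SRRM1 and SRSF12 held none. Genes of the core spliceosome held a region in 6 of 26 cases against 1.57 (adjusted permutation p = 0.014), with 3 regions in PRPF8, the central scaffold protein of the spliceosome, 1 each in SNRPB, SNRPD1 and SNRPF, and none in EFTUD2 and PRPF19. In the stricter 50% of each list by p-value, 2 core spliceosome genes held a region and the adjusted permutation p was 0.84, and with 1 replicate left out 9 to 12 did. All p-values for lists come from two-sided permutation tests.

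Genes for proteins described as binding or unwinding G-quadruplexes held a region in 14 of 24 cases against 1.75 in random lists (adjusted permutation p = 0.0004). NCL, the gene of nucleolin, and SERBP1, which encodes a ribosome-associated RNA-binding protein, held 8 regions each, of which 2 of those in NCL were named jointly with the small nucleolar RNAs SNORD20 and SNORD82 that lie within it, and the helicase genes DDX3X and DDX5 held 7 each. The helicase genes BLM and BRIP1 held none. Messenger RNAs described as carrying RNA G-quadruplexes held a region in 2 of 16 cases against 1.11 (adjusted permutation p = 0.71). APP, the gene of the amyloid precursor protein, held 1 region, and ADAM10 and BCL2 held none. Messenger RNAs with AU-rich elements, which mark short-lived transcripts, held a region in 1 of 23 cases against 0.76 (adjusted permutation p = 1), in MCL1 with 3 regions, while ATF3 and CCND1 held none. Of these 23 genes, 5 had a peak in any replicate, and 1 to 3 held a region with 1 replicate left out.

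Genes of the translation apparatus and abundant housekeeping proteins also held regions often. Cytoplasmic ribosomal protein genes held one in 41 of 89 cases against 3.03 in random lists (adjusted permutation p = 0.0004), with 10 regions in RPL4, 6 in RPS3, and none in FAU and RPL10A. RPL7L1, a ribosomal-protein-like gene that the naming pattern of the list took in, held 4. Translation initiation and elongation factor genes held one in 22 of 70 cases against 4.42 (adjusted permutation p = 0.0004). EIF4G2 held 13 regions, EIF4B 8, EEF1A1 7 and EIF3E 6, and EEF1A2 held none. EEF1AKMT1, a methyltransferase gene that the naming pattern of the list took in, held none either, so not all 70 genes encode such factors. Chaperone genes did so in 16 of 23 cases against 1.31 (adjusted permutation p = 0.0004), led by the mitochondrial chaperone gene HSPD1 with 6, HSP90B1 and HSPA8 with 4 and HSPE1 with 3, while CCT4 and CCT7 held none. Cytoskeleton and glycolysis genes did so in 13 of 22 cases against 1.09 (adjusted permutation p = 0.0004), with 4 regions each in LDHB, PKM and TUBA1B and 3 in ACTG1, and none in ALDOA and GPI.

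Proteasome subunit genes held one in 3 of 39 cases, PSMA2, PSMD1 and PSMD12, against 2.10 in random lists (adjusted permutation p = 0.76), and PSMA1 and PSMA3 held none. In regions found in 2 or more replicates, 10 proteasome genes were counted and the adjusted permutation p was 0.02, and with 1 replicate left out 5 to 7 were counted. Nuclear-encoded respiratory chain genes held one in 9 of 85 cases against 3.77 (adjusted permutation p = 0.028), with 2 regions each in ATP5F1A, ATP5MC3, COX7C and NDUFS1, and none in ATP5F1C and ATP5F1D. That call was lost in the stricter 50% of each list, with 5 genes and an adjusted permutation p of 0.43, without replicate 1, with one of 0.21, and without matching on length, with one of 0.24. Replication-dependent histone genes, which are short and lack introns, held one in 5 of 68 cases against 0.90 (adjusted permutation p = 0.0045), with 2 regions in H1-2 and 1 each in H2AC13, H2AC6 and H3C10, and none in H1-1 and H1-3. Without matching on length the adjusted permutation p for histones was 0.92, and with 1 replicate left out 5 to 10 of them held a region. Of 34 genes typical of other tissues, such as ALB and ACTA1, none held a region and 1 had a peak in any replicate, against 1.38 in random lists (adjusted permutation p = 0.62). RNA levels were not measured in these files, so none of the list counts separates binding from the abundance of the transcripts.

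**Figure D5:**
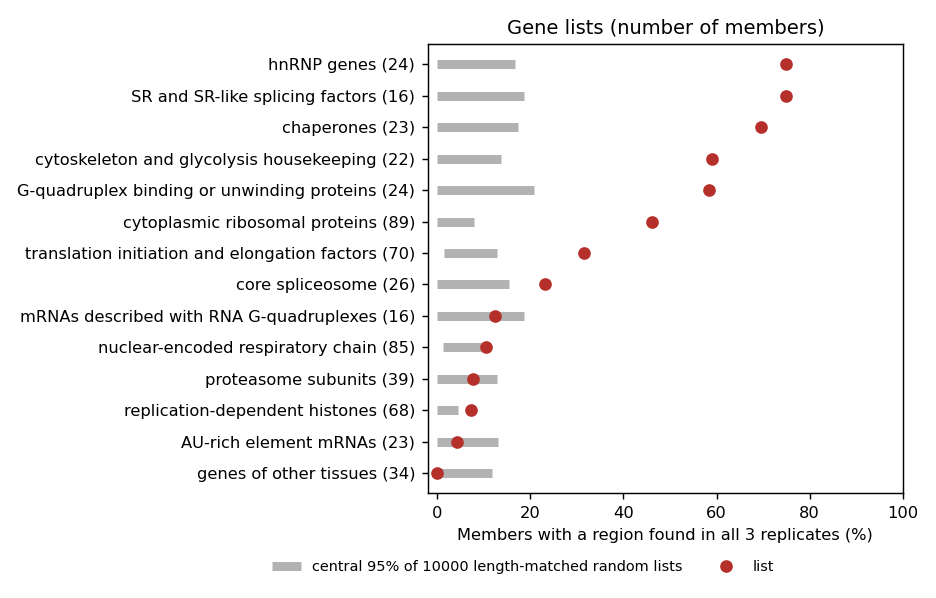
Share of the members of each tested gene list that held a region found in all 3 replicates (red points, x axis in percent), with the central 95% of 10000 random lists matched on gene length (grey bars) and the number of members in brackets. The hnRNP list reached 18 of 24 members and the list of genes typical of other tissues 0 of 34.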

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

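The overlap between replicates, the number of peaks, the positions along the gene, the regions of the HNRNPA0 gene and 10 of the 16 gene lists kept their direction and their side of the threshold, or stayed within the limits set for a count, under every alternative run. The overlap ranged from 16.6% with 50% of both peaks required to 35.1% with the stricter 50% of each list, and in the final 10% of the gene the share of regions ranged from 38.5% to 44.7%. The number of regions moved from 2372 to 7191 when 2 or more replicates sufficed, to 1382 with an overlap of 50% of both peaks, and to between 3909 and 3976 with each replicate left out, since a region then needed 2 lists. Genes with a region came to 2687 when 2 or more replicates sufficed. The core spliceosome list was no longer past the threshold with the stricter 50% of each list (2 genes, adjusted permutation p = 0.84). The respiratory chain list was no longer past it in that 50% (5 genes, adjusted permutation p = 0.43), without replicate 1 (9 genes, adjusted permutation p = 0.21, and 9 to 12 genes over the replicates left out) or without matching on length (9 genes, adjusted permutation p = 0.24), and neither were the histones without that matching (5 genes, adjusted permutation p = 0.92). The proteasome list passed it with regions in 2 or more replicates (10 genes, adjusted permutation p = 0.02). The mitochondrial list fell to 0 on chromosomes 1 to 22 and X by construction. The cause of the other changes was not tested. No result past its threshold changed direction. Among lists not past it, the AU-rich list held fewer members than random lists without matching on length (1 against 1.42) and without replicate 1 (1 against 1.01), with 1 to 3 members over the replicates left out, and the proteasome list did in the stricter 50% (1 against 1.53). Of the 67 named genes, 12 changed their number of regions by over 1.5 times with the stricter 50% of each list and 27 with 2 or more replicates, and 10, 12 and 9 did without replicates 1, 2 and 3. The shift of 200 to 1000 nt and the alternatives for peak numbers, for positions along the gene and for the HNRNPA0 gene were chosen after seeing the data. Alternatives that need a genome sequence or exon annotation (all for motifs and transcript features, placement with exons apart, and regions in exons only) were not run. No paired analysis was possible because all samples form 1 group, and for the same reason there are no other splits of the samples. The median read number of 4 limits what the lists can show, and no subsampling was run to separate low depth from other sources of peaks seen in 1 replicate.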

Other observations

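All tests in this part were chosen after the results they bear on had been seen.

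Gene families grouped by symbol prefix showed both extremes of the lists. Of 148 families tested with at least 15 members, 4 held regions more often and 3 less often than random genes of the same length at an adjusted p under 0.05. The EIF, RPL and RPS families repeat lists of the report. The RBM family of RNA-binding motif proteins held a region in 9 of 39 genes against 2.60 in random lists (adjusted permutation p = 0.0465). The ZNF family of zinc finger proteins held one in 13 of 517 genes against 34.1 (adjusted permutation p = 0.00592). Olfactory receptor genes held one in 1 of 392 genes against 10.1 (adjusted permutation p = 0.0345). The third family below random lists, protein-coding loci without a given symbol, is not weighed, since the naming of regions set such loci aside. These permutation tests are two-sided. They were not matched on RNA levels, so the family counts do not separate binding from the abundance of the transcripts.

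Several short structured RNAs, picked after their values were seen, held regions in all 3 replicates. SNORD3A, a U3 small nucleolar RNA gene, had highest read numbers of 146, 139 and 152 on chromosome 17 from 19188042 to 19188216. RN7SK, which holds the elongation factor P-TEFb inactive, had 134, 141 and 181 in its stronger region. RMRP, the RNA of RNase MRP, had 83, 72 and 75, and RNU12, the U12 small nuclear RNA, had 67, 74 and 65. VTRNA1-2, a vault RNA, had 57, 69 and 73, and RPPH1, the RNA of RNase P, had 47, 40 and 39. Other short RNA genes differed more between replicates, such as RNU6-9, a U6 small nuclear RNA gene, with 66, 72 and 25.

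The peaks of the HNRNPA0 gene lay in one stretch of 899 nt, where 98.5% of their summed read number fell. No biological difference between groups could be tested. Of 75 other genes given as protein-coding in the RefSeq table, which include TUG1, with at least 5 peaks per replicate and a length from 0.5 to 2 times that of HNRNPA0, 0 were as concentrated in their best 1000 nt, where their median was 48.4%, and 4 were in their best 500 nt. The windows were measured along the genome with introns included. This comparison therefore cannot separate concentrated binding from the layout of exons in each gene. RNA or DNA of the transfected vector and binding to the cell's own HNRNPA0 mRNA in that stretch alone may each give such values and cannot be told apart, since the highest peak outside the stretch had a read number of 9 and no library without the vector was used here.

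Replicate 3 had a higher share of signal in XIST and a lower share in RNR1 than the other replicates, while RNR2 (14.4%) lay between them (13.8% and 18.2%) and ND4 (0.572%) lay above them (0.338% and 0.399%). Whether greater depth of replicate 3 is the source cannot be decided by comparing regions. A higher share of XIST already means a higher ratio for its regions than for others. Regions with a mean read number of 20 or more were compared by the log2 ratio of replicate 3 to the mean of the other replicates. The median was 0.74 over 30 XIST regions, which are parts of 1 RNA, and 0.02 over 300 other nuclear-encoded regions, a difference of 0.722. The upper quartile of the other regions was 0.32. The other regions thus showed little general rise in replicate 3. Counting the same reads in neighbouring peaks is argued against as the whole source, though it may be part of it. The XIST share in replicate 3 was 1.62 times the mean of the others with all peaks summed. With touching peaks counted once it was still 1.41 times. The mitochondrial share was 0.768 times the mean of the others with all peaks summed, and 0.738 times with touching peaks counted once. A better recovery of nuclear noncoding RNA in general cannot be told apart from an XIST difference, because 15 regions of the listed noncoding RNAs with a mean read number of 20 or more had a median of 0.28 above the other regions with quartiles of -0.02 and 0.61, and all 41 regions of the listed RNAs a median of 0.136. Those 15 regions came from 7 genes, and 7 of the regions were in MALAT1, so their median rests largely on 1 gene. Of the 30 XIST regions 29 lay above the median of the other regions, and no biological explanation was tested, since the labels give the replicates no difference.

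The hnRNP genes held regions more often than core spliceosome genes, in 18 of 24 against 6 of 26 cases (two-sided Fisher's exact p = 0.00053, adjusted p = 0.0014 over 3 tests), and the SR genes did so in 12 of 16 cases (two-sided Fisher's exact p = 0.0014, adjusted p = 0.0014). With 1 replicate left out the core spliceosome count rose to between 9 and 12 and the hnRNP count to 19 or 20. The two-sided Fisher's exact p for hnRNP genes against core spliceosome genes, not adjusted, was then at most 0.022, without replicate 1. On chromosomes 1 to 22 and X without the HNRNPA0 gene it was 0.0015, with 17 of 24 hnRNP genes. Without replicates 1, 2 and 3 in turn, the SR count was 12, 12 and 14 of 16. The core spliceosome count was then 12, 11 and 9 of 26, and the SR difference was not tested there. Gene length is argued against as the source, since random lists matched on length held nearly equal numbers for the 2 lists. They gave 1.41 genes with a region for the 24 hnRNP genes and 1.57 for the 26 core spliceosome genes. Among genes of 5 to 40 kb, 16 of 19 hnRNP genes and 6 of 20 core spliceosome genes held a region (two-sided Fisher's exact p = 0.0011, adjusted p = 0.0014). That range kept most genes of both lists, so it is no separate test of length. Abundance of the transcripts may account for the difference and cannot be told apart from binding: 22 of 26 core spliceosome genes and 23 of 24 hnRNP genes had a peak in any replicate, and no RNA levels are among the values used here.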
